A study of Synechocystis sp. PCC 6803 with 8 samples.

How the data were processed

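The study grew glucose-tolerant Synechocystis sp. PCC6803, a unicellular cyanobacterium, and compared 4 conditions with 2 sequencing libraries each, 8 libraries in all. Per the labels' protocols, cells grew in BG-11 medium at 30 °C and 20 PPF (photosynthetic photon flux) with air holding 1% CO2, and were treated at an optical density of 0.8 at 730 nm. Treated cells spent 30 min at 300 PPF (high light), at 24 °C (low temperature) or at both together (combined stress), and untreated cells were the control. The labels describe experiments in triplicate and libraries in duplicate, and do not say which culture a library came from. Per the labels' protocols, ribosomal RNA was depleted, 50 ng of the remaining RNA went into a directional ScriptSeq v2 library with 10 cycles of PCR, and the libraries were read on an Illumina MiSeq. The kit marks the strand of the RNA. Some reads may still keep the wrong strand, so the strand of weak pieces opposite abundant transfrags is not secure.

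The deposited files hold transfrags, which are stretches of a replicon and strand called as transcribed by the submitters. The submitters' processing notes name CASAVA 1.4 and DESeq. The aligner, the method that called transfrags and the name of the genome build are not given in the sources used here. Coordinates are printed as the deposited files give them, counted from 1, on the chromosome and the 4 plasmids pSYSM, pSYSA, pSYSG and pSYSX. The annotation lists 16368 transfrags, of which 48 have no entry in the expression table and 28 have an entry without values, so 16292 have values. Their lengths run from 21 to 16441 bases with a median of 64.0, so a transcript is often broken into several transfrags.

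Per the file headers and the submitters' processing notes, the deposited signal values are read counts scaled with DESeq, given as 1 value per group with 2 decimals. No values per library and no counts are given. Low values are sums of whole reads of the pair of libraries, each read being worth a fixed step, so they show that the authors averaged both libraries of a group after scaling. The steps were found by a search for the pair that explains every value below 25 within 0.0051, and they explained 100.0% of these values in each group. Between 29.6% and 43.3% of all numbers with 2 decimals would be explained by chance. The steps give size factors of 1.133 and 0.484 for the control, 1.038 and 0.772 for high light, 1.476 and 0.908 for low temperature, and 1.808 and 1.17 for combined stress. If both libraries of a group have the same scaled total, these correspond to about 6500000 and 2800000 reads in transfrags for the control, 8900000 and 6600000 for high light, 10300000 and 6300000 for low temperature and 8200000 and 5300000 for combined stress. A value of 10 then stands for about 11.3 and 4.8 reads in the control libraries, and for 18.1 and 11.7 in those of combined stress. A step cannot be tied to a replicate number of the labels. The steps of combined stress, and the numbers drawn from them, are uncertain, as described below.

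The plan fixed before the data were examined was a limma fit to the 8 libraries with 4 residual degrees of freedom. With 1 value per group that test could not be run. No p-value is given for the group values of a transfrag or for counts of transfrags by fold. P-values of single transfrags come only from the weak ones whose libraries could be read back. Differences are on the scale of log2(value + 1), which understates those of low values, for the 14567 transfrags with a mean of at least 10 over the 4 groups. Transfrags at least 2-fold and at least 4-fold apart were counted, and each count stands beside the mean of 50 simulations in which all groups share one mean per transfrag. Simulated libraries have the recovered size factors and the spread found between the libraries of a group. That spread was estimated by maximum likelihood over all pairs of whole reads that could give a value, for values from 10 to 25. It came to a dispersion of 0.095 in the control, 0.15 in high light, 0.095 in low temperature and 0.095 in combined stress, or coefficients of variation of 30.8%, 38.7%, 30.8% and 30.8%. The same dispersion was used at every level. For values from 25 to 40 and from 40 to 60 it was 0.085 and 0.08 in the control, 0.11 and 0.125 in high light, 0.02 and 0.025 at low temperature, and 0.085 and 0.09 under combined stress. The simulated spread is therefore too wide at low temperature for values from 25 to 60, and somewhat too wide in the control and high light. Above 60 the dispersion could not be measured, and the simulations and printed errors there rest on the value found at 10 to 25. A second set of 50 simulations with the dispersion found level by level, taking that of 40 to 60 for all values above, was added after seeing the data. In data simulated for low temperature, dispersions of 0.095 and 0.02 came back as 0.08 to 0.09 and as 0.02. In data simulated for combined stress with 0.095, other steps were found and the estimate was 0.20, the highest value searched. The dispersion of that group is therefore uncertain, and so are its steps, size factors and read numbers. The error printed with a named transfrag is the SD of its log2 difference that this dispersion and counting imply. The simulations cover the spread between these libraries, which may be technical.

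The transfrags named are, for each comparison, those with the largest log2 difference in each direction. The fixed rule asked for gene names, locus tags and adjusted p-values, none of which the deposited files allow. The reference table of genes belongs to a different assembly and shares no identifier with the transfrags, so no name was assigned and the gene lists fixed in advance could not be tested. Without names, at most 2 transfrags higher and 2 lower are printed per comparison. Regions are runs of at least 4 neighbouring transfrags of one strand, at most 1000 bases apart, all at least 2-fold higher or all at least 2-fold lower. Their number was compared with 100 shuffles of the differences along the replicons. The shuffles ask whether such transfrags lie side by side, as pieces of one transcript do with or without a treatment, and not whether a region lies beyond the spread between libraries. A transfrag counts as an opposite-strand piece when a longer transfrag on the other strand covers at least 50% of it. Without annotated genes, this class stands in for antisense RNA. Medians of classes were set against 10000 random lists of the same size matched on mean value and not on length. The lists draw transfrags singly, while neighbours in a class can have similar differences, so a percentile may overstate how unusual a class is. Correlations between pairs have permutation p-values from 100000 permutations, two-sided. Pairs and transfrags are not independent replicates.

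For weak transfrags the reads of each library can be read back from the steps. This was done for control and high light where the mean of low temperature and combined stress lay from 10 to 20, which selects transfrags by groups outside the comparison. Of 2238 such transfrags, 2151 (96.1%) gave a single pair of read numbers in both groups, and their scaled values were tested with limma 3.58.1. This test was chosen after seeing the data. Pairs of read numbers are ambiguous in most values of low temperature and combined stress, where 30.6% and 19.8% of values below 25 have a single solution, so the reads of those groups were not recovered.

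The steps, the counts and the limma test were tested on simulated data. The search for steps was revised after it failed on simulated data in which one step was close to double the other. With the final search, 97.5%, 100.0%, 99.5% and 89.5% of the unique pairs of reads were right for data simulated like control, high light, low temperature and combined stress, and 69.6% in the difficult case, which remains unsolved. The revision left the steps of the deposited values as they were. In weak transfrags simulated for high light against control with a dispersion of 0.1, 53.0% of 2-fold and 86.0% of 4-fold differences reached 2 fold. A true 2-fold difference lies at the cutoff itself, so its share does not measure the effect of depth. The limma test on recovered libraries called 0.0% of 68 simulated 2-fold and 0.0% of 51 simulated 4-fold differences, so a lack of calls there carries no information.

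Alternatives fixed before the data were examined were pseudocounts of 0.5 and 10, no filter and a filter at a mean of 50, TMM scaling, quantile normalization, a 90% overlap for opposite-strand pieces, and pairs whose opposite-strand piece reaches 5% of its partner. Scaling every group to the same total was added after seeing the data, because the deposited totals differ. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3.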

Results

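RNA of Synechocystis sp. PCC6803 was sequenced by strand in 4 groups of 2 libraries: control cells at 20 PPF and 30 °C, cells after 30 min at 300 PPF, cells after 30 min at 24 °C, and cells given both for 30 min. The layout asks how transcripts on either strand differ under each stress, and whether the difference made by light is the same at both temperatures. The series title places the question in antisense RNA and the photosynthetic response. Expression is given as the authors' normalized value of each group for 16292 transfrags, with a median of 40.02, and no value has a replicate of its own. The sum of the values was 5712015 in the control, 8575326 in high light, 6976897 at low temperature and 4554669 under combined stress. The 20 most abundant transfrags held 45.0%, 48.3%, 50.8% and 40.3% of these sums.

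In high light at 30 °C, the largest differences above the control on the scale of log2(value + 1) lay in 1 stretch of the chromosome. Transfrag008923 (minus strand, 3071969 to 3071996) had a value of 485.86 against 6.92 in the control, 70.2-fold higher, a log2 difference of 5.94 (expected SD 0.69). Its control value rested on libraries at 9.71 and 4.13. Transfrag008922 (minus strand, 3071892 to 3071949) was 42.6-fold higher, at 3011.82 against 70.65 (log2 difference 5.39, expected SD 0.53). Both belong to a region of 6 neighbouring transfrags from 3070818 to 3071996 with a median log2 difference of 4.96. In the other direction, Transfrag015778 (plus strand, 2215953 to 2216835) was 38.4-fold lower, at 255.25 against 9789.92 (log2 difference -5.26, expected SD 0.51). Transfrag017605 (plus strand, 2949843 to 2950383) was 11.2-fold lower, at 85.94 against 964.83 (log2 difference -3.47, expected SD 0.52).

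Further regions stood well above the control in high light. On the minus strand of the chromosome, 5 transfrags from 3064820 to 3066232 had a median log2 difference of 3.68, 7 from 957868 to 960124 one of 3.47, and 4 from 2728400 to 2730251 one of 3.65. On the plus strand, 4 transfrags from 1600529 to 1602125 had a median of 3.92. The region with the most members held 16 transfrags from 1111599 to 1116991 on the minus strand, with a median of 2.12. Plasmid pSYSX carried a pair of regions of 13 transfrags each on its plus strand, from 34756 to 39257 (median 2.26) and from 39931 to 42781 (median 2.28). Regions below the control included pSYSA, the plasmid that carries CRISPR loci, from 39778 to 43708 on the plus strand (12 transfrags, median -1.64) and from 69273 to 73407 on the minus strand (12 transfrags, median -1.70). Neighbouring transfrags can be pieces of one transcript, so a region may stand for a single RNA.

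Of 14567 transfrags, 1536 were at least 2-fold higher and 2480 at least 2-fold lower in high light, 4016 in all, where simulated unchanged groups gave 1170. At least 4-fold apart were 437, with 15.8 in simulations. There were 71 regions higher and 79 lower, against shuffled means of 1.5 and 7.1. These 150 regions became 68 with a pseudocount of 10 or quantile normalization and 338 with equal totals. The direction depended on abundance: the median log2 difference was -0.28 for transfrags with a mean of 10 to 50, 0.13 for 50 to 200, 0.43 for 200 to 1000 and 0.55 for 1000 and above. Scaling each group to the same total moved the median of all transfrags to -0.58 and gave 457 higher and 4888 lower. The abundant transfrags were then level with the control (median -0.04 at 1000 and above) and those of 10 to 50 lay at -0.83, so relative values do not say which end of the range moved.

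**Figure D1:**
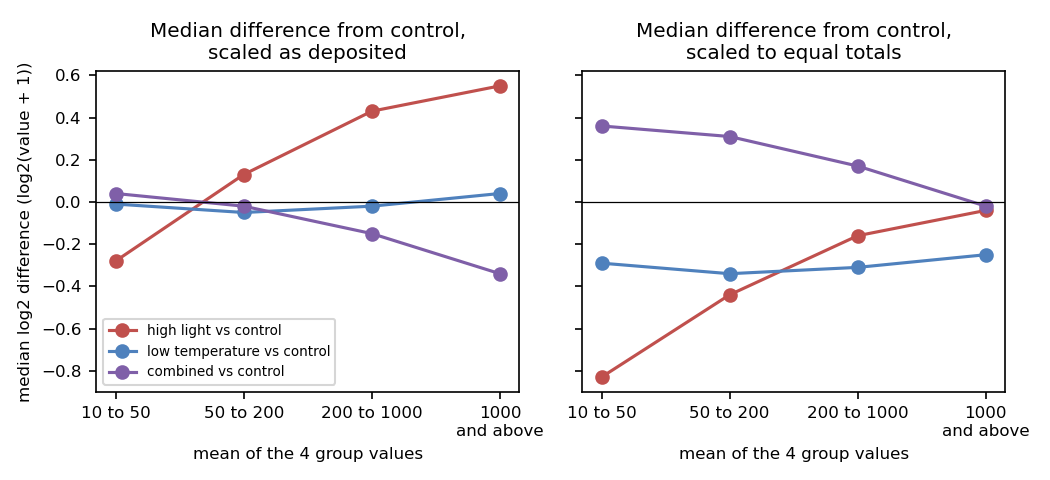
Median log2 difference from control (vertical axis, log2 of value + 1) of high light, low temperature and combined stress, for transfrags grouped by the mean of the 4 group values (horizontal axis), as deposited at left and scaled to equal totals at right. In high light the median runs upward with abundance, from -0.28 to 0.55 as deposited and from -0.83 to -0.04 with equal totals.

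At 24 °C and 20 PPF, a small set of abundant chromosomal transfrags was far above every other group. Transfrag002660 (minus strand, 460165 to 460742) had a value of 16936.78 against 670.15 in the control, 25.3-fold higher (log2 difference 4.66, expected SD 0.45). Transfrag004770 (minus strand, 1353491 to 1353930) was 18.3-fold higher, at 16187.88 against 883.81 (log2 difference 4.19, expected SD 0.45). The transfrags furthest below the control were Transfrag000723 on plasmid pSYSG (minus strand, 17487 to 17533), at 22.58 against 304.2, 13.5-fold lower (log2 difference -3.69, expected SD 0.49), and Transfrag001880 (chromosome, minus strand, 122066 to 122121), at 4.28 against 57.08 (log2 difference -3.46, expected SD 0.66). Control libraries of Transfrag001880 stood at 33.5 and 80.6.

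In all, 25 transfrags were more than 3 times higher at low temperature than in each other group, where simulated unchanged groups gave 0.0. All 25 lay on the chromosome, with a median mean value of 2161 and a median length of 690.0 bases. Of these, 6 lay opposite another of the 25. The other 19 were a median of 5.51-fold above the control (3.52 to 25.3). Under combined stress 16 of the 19 had a value below the control, at a median of 0.466 times the control value, and in high light alone 13 of 19 were below, at a median of 0.67 times.

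**Figure D2:**
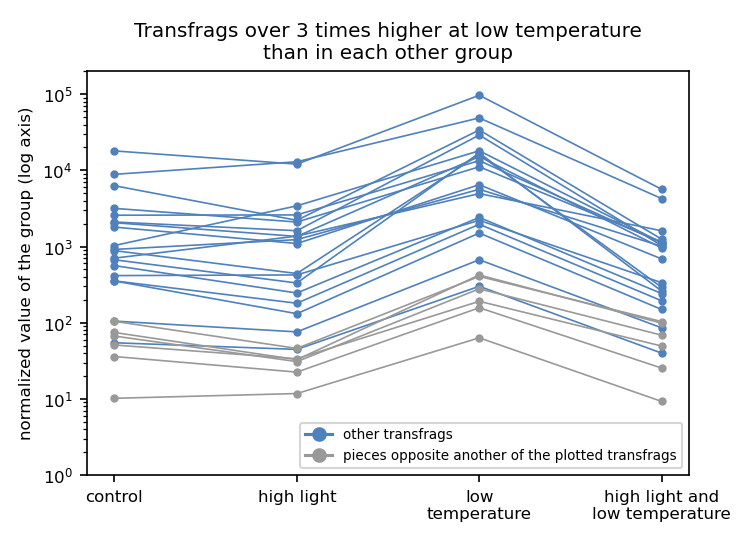
Normalized value on a log axis in the 4 groups (horizontal axis) for the 25 transfrags more than 3 times higher at low temperature than in each other group, 1 line per transfrag, with the 6 pieces lying opposite another of the 25 in grey. The transfrags were chosen for this peak, so every line is highest at low temperature and lower under combined stress by the rule of choice.

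Of the 7 regions lower at low temperature, 4 lay between 1184989 and 1197282 on the chromosome. From 1190785 to 1193970 on the plus strand, 13 transfrags had a median log2 difference of -1.66, and from 1186270 to 1189859 on the minus strand 13 had a median of -1.26. Next to them, 6 transfrags from 1196427 to 1197282 (plus strand) had a median of -1.64 and 4 from 1184989 to 1185781 (minus strand) one of -1.24. These 4 regions had medians of -0.17, 0.19, 0.38 and 0.36 in high light and of -1.26, -0.76, -0.84 and -0.80 under combined stress. Of the 3 regions higher at low temperature, the one from 2312636 to 2314206 (plus strand, median 2.02) and the one from 3514215 to 3515629 (plus strand, median 1.26) lay opposite abundant transfrags of the 25; pieces opposite transfrags of 10000 and above stood at a median of 1.79% of them in general. The third, from 1600529 to 1602125 on the plus strand, was higher in every stress, with medians of 1.71 at low temperature, 3.92 in high light and 2.39 under combined stress.

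At low temperature 354 transfrags were at least 2-fold higher and 347 lower, 701 in all. Simulated unchanged groups gave 754 with the dispersion of values from 10 to 25 at every level, and 421 (at most 459) with the dispersion found level by level, so the choice decides whether this count exceeds the spread between libraries. At least 4-fold apart were 58, against 6.1 and 4.8 in these simulations. Of transfrags of 1000 and above, 51 were higher and 12 lower, against 8.0 and 7.3 in the first simulations; with equal totals they were 34 and 29, with a median of -0.25. Shuffles gave 0.0 and 0.0 regions higher and lower. Equal totals moved the median to -0.31, gave 158 higher and 931 lower, and made 17 regions of the 10.

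Under combined stress, several of the stretches that stood out in high light were again above the control. Transfrag008900 (minus strand, 3065316 to 3065352) was at 95.42 against 3.68 in the control (log2 difference 4.36, expected SD 0.79), with control libraries at 5.3 and 2.07. Transfrag008923 was 20.7-fold higher, at 142.91 (log2 difference 4.18, expected SD 0.65). Transfrag016203 (plus strand, 2376873 to 2377519) was 16.1-fold lower, at 797.71 against 12836.59 (log2 difference -4.01, expected SD 0.45), and Transfrag015778 was 13.4-fold lower, at 730.22 (log2 difference -3.74, expected SD 0.45). The region from 957868 to 960124 (minus strand) had a median of 3.72, that from 3070818 to 3071996 one of 3.27, and the 13 transfrags from 2769037 to 2773994 (plus strand) one of 1.41, against 1.96 for the same 13 in high light alone. A region of 9 transfrags from 858965 to 862087 (plus strand) had a median of 1.67 under combined stress, 0.55 in high light and 0.66 at low temperature. The region lower over the most transfrags was the one also lower at low temperature, with 15 transfrags from 1191449 to 1194837 and a median of -1.33.

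Under combined stress 670 transfrags were at least 2-fold higher and 469 lower, 1139 in all against 718 in simulations, and 120 were at least 4-fold apart against 5.0. There were 22 regions higher and 17 lower, against shuffled means of 0.0 and 0.0. Equal totals moved the median to 0.31 and gave 1477 higher and 183 lower. Medians by abundance went the other way from high light, from 0.04 at 10 to 50 to -0.34 at 1000 and above, where 70 were lower and 27 higher; with equal totals that last median was -0.02.

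The interaction, which is the light difference at 24 °C minus that at 30 °C, was most negative in abundant transfrags. Transfrag012767 (plus strand, 982925 to 983648) was 3.32 times the control value in high light at 30 °C, and at 24 °C light left it at 0.0621 times the low temperature value, 1124.38 against 18093.54 (interaction -5.74 in log2, expected SD 0.67). Transfrag002660 was 0.496 times the control value in light at 30 °C and 0.0153 times the low temperature value in light at 24 °C (interaction -5.01, expected SD 0.68). Both are among the 25 transfrags highest at low temperature alone, so these interactions rest largely on their low temperature value. Whether both low temperature libraries carry that value cannot be told. In the other direction, Transfrag016066 (plus strand, 2317297 to 2317336) had an interaction of 3.87 (expected SD 0.85) on values of 31.34 in the control, 11.48 in high light, 8.89 at low temperature and 54.81 under combined stress. Its control value rested on 1 library, at 56.5 beside 6.20 in the other. Transfrag004337 (minus strand, 1175408 to 1175451) had an interaction of 3.48 (expected SD 0.89). It was at 5.17 in high light against 39.82 in the control, and at 29.32 under combined stress against 16.98 at low temperature. Its control libraries stood at 23.8 and 55.8, and its high light value rested on 4 and 5 reads. Among the 20 most abundant transfrags the interaction was below 0 in 20 as deposited, and at least 2-fold in 14. Both counts depend on the scaling, since equal totals moved the median interaction of transfrags of 1000 and above from -0.90 to 0.30.

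The interaction was at least 2-fold in 2919 transfrags upward and 1694 downward, 4613 in all against 2643 in simulations, and at least 4-fold in 535 against 130.5. Its median was 0.36 for transfrags of 10 to 50 and -0.90 at 1000 and above. Equal totals moved the median of all transfrags to 1.18 and gave 8346 upward and 99 downward, and the median at 1000 and above was then 0.30. Quantile normalization gave 1827 and 1623, and a filter at a mean of 50 turned the majority downward, with 746 and 1054.

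Beside high light alone, the transfrags furthest lower under combined stress were Transfrag008114 (minus strand, 2729392 to 2730251), at 1787.79 against 13216.75 (log2 difference -2.89, expected SD 0.51), and Transfrag011365 (plus strand, 452204 to 452241), at 21.00 against 152.43 (log2 difference -2.80, expected SD 0.55). Transfrag001647 (minus strand, 34490 to 34568) was 11.3-fold higher under combined stress, at 52.80 against 4.68 (log2 difference 3.24, expected SD 0.72). Its high light value rested on 3 and 5 reads. Its value under combined stress was close to its control value of 50.87, for which the libraries stood at 33.5 and 68.2. Transfrag019230 (pSYSA, minus strand, 39495 to 39523) was at 23.54 against 1.61 (log2 difference 3.23, expected SD 1.01), a high light value that rested on 2 and 1 reads. At least 2-fold higher than in high light alone were 2854 transfrags and lower 1279, 4133 in all against 1028 in simulations. Equal totals moved the median to 0.79 and gave 6186 and 19, and a filter at a mean of 50 gave 718 and 894.

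Beside low temperature alone, combined stress had its largest differences upward in the same chromosomal stretch as high light at 30 °C. Transfrag008923 was 30.4-fold above low temperature alone, at 142.91 against 4.70 (log2 difference 4.66, expected SD 0.63), and Transfrag008920 (minus strand, 3071581 to 3071622) was 21.7-fold above, at 235.63 against 10.84 (log2 difference 4.32, expected SD 0.54). Transfrag002660 and Transfrag004770 were 65.2-fold and 55.6-fold lower than at low temperature alone (log2 differences -6.02 and -5.79, expected SD 0.45 each). Both are among the 25 transfrags highest at low temperature alone, so these differences rest largely on the same low temperature values as above. In all 558 were at least 2-fold higher and 362 lower, 920 against 601 in simulations, or 313 with the dispersion found level by level. Equal totals moved the median to 0.64 and gave 2888 and 89.

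**Figure D3:**
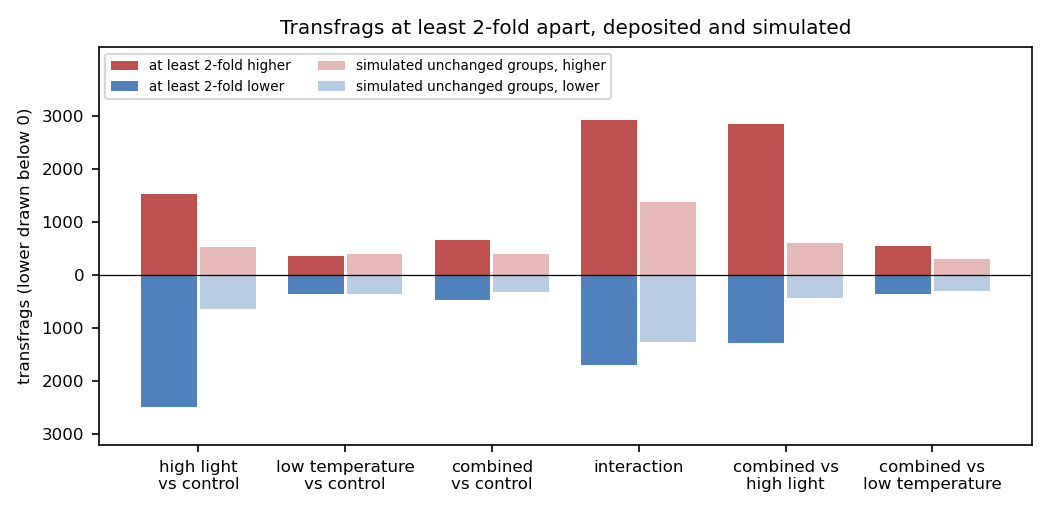
Number of transfrags at least 2-fold higher (above 0) and lower (below 0) in the 6 comparisons, as deposited (dark bars) and as the mean of 50 simulations of unchanged groups (pale bars). High light against control reached 4016 against 1170 in simulations, and low temperature against control 701 against 754, or 421 in simulations with the dispersion found level by level, which are not drawn.

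Light differences at 30 °C and at 24 °C come from separate libraries and could be compared directly. Both were at least 2-fold upward in 275 transfrags, where independent lists would share 58.8 and simulated unchanged groups 12.3, and at least 4-fold upward in 40, where independent lists would share 1.0. Downward they shared 69 at least 2-fold, where independent lists would share 61.6 and simulations 13.7, and 7 at least 4-fold, where these gave 0.7 and 0.0. Across transfrags Pearson's r was 0.22 and Spearman's rho 0.12 (simulated r 0.00); r was 0.55 over the 2029 transfrags with a mean of 200 or more and 0.13 over those under 50. Temperature differences at the 2 light levels shared 106 transfrags upward and 88 downward, where independent lists would share 69.4 and 30.5, with r 0.14. At least 4-fold they shared 0 upward and 0 downward. At least 2-fold in opposite directions were 71 transfrags for temperature and 41 for light.

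Comparisons that share the control libraries share their chance values. High light and combined stress shared 318 upward and 135 downward, against 132.3 and 60.2 in simulations and 70.6 and 79.8 for independent lists, with a covariance of 0.195 beside 0.14 simulated (r 0.35 beside 0.48). High light and low temperature shared 106 and 60, against 133.5 and 62.2 in simulations and 37.3 and 59.1 for independent lists, with a covariance of 0.08 beside 0.14 (r 0.17 beside 0.48). Low temperature and combined stress shared 139 and 115, against 130.9 and 47.1 in simulations and 16.3 and 11.2 for independent lists, with a covariance of 0.143 beside 0.14 (r 0.48 beside 0.54). The overlap of high light with low temperature, 166 in both directions together, was 437 with equal totals and 62 with a pseudocount of 10. Part of each overlap may come from the shared control. It was not split, because each part would hold 1 library and values per library could not be had for most transfrags.

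Transfrags of the 4 plasmids had lower medians in high light than random transfrags of like level. Median log2 differences from the control were -0.34 for pSYSM (443 transfrags), -0.69 for pSYSA (360), -0.58 for pSYSG (234) and -0.61 for pSYSX (414). Each lay at percentile 0.0 of 10000 random lists matched on mean value, of which the lowest medians were -0.26, -0.36, -0.34 and -0.30. Plasmid pSYSX went both ways, with 42 of its transfrags at least 2-fold higher, among them the regions from 34756 to 42781, and 139 lower. Under combined stress its median was 0.21 (percentile 100.0), with 47 higher and 5 lower, and the medians of pSYSA, pSYSG and pSYSM were 0.14, 0.12 and 0.02 (percentiles 100.0, 99.9 and 73.7). The lists draw transfrags singly, while neighbours of one strand had similar differences in high light (rho 0.63). The percentiles may therefore overstate how unusual a plasmid is. Plasmid transfrags had median lengths of 58.5 to 67.0 bases against 74.0 on the chromosome, and length was not matched. These percentiles describe these libraries and have no replicate check.

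Opposite-strand pieces, the 2589 transfrags lying against a longer one on the other strand, were also lower in high light, with a median of -0.49 (percentile 0.0 of matched random lists), and higher under combined stress, with a median of 0.21 (percentile 100.0). At least 2-fold apart from the control were 35.3% of them against 25.9% of other transfrags in high light, 6.3% against 4.5% at low temperature and 13.9% against 6.5% under combined stress. With a pseudocount of 10 the 9.4 points of excess in high light came to 1.2 points. Pieces had a median length of 57.0 bases against 80.0 for other transfrags. The random lists were not matched on length and draw transfrags singly, so these percentiles may also be overstated. In 913 of 2569 pairs the piece was under 2% of its partner, and such pieces may be reads that kept the wrong strand. The medians and shares of the class may therefore not be those of antisense RNA.

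Pieces and the transfrags they lie against were compared in 2569 pairs. Spearman's rho between their log2 differences was 0.09 in high light, 0.18 at low temperature and 0.06 under combined stress (adjusted permutation p 1.5e-05, 1.5e-05 and 0.005 over 3 relations), with Pearson's r of 0.12, 0.28 and 0.17. The sign depended on how strong the piece was. In the 913 pairs whose piece was under 2% of its partner, rho was 0.39, 0.33 and 0.39, while in the 346 pairs with a piece at 50% or more it was -0.23, -0.01 and -0.02. Among the 955 pairs at 10% or more, 30 had a piece at least 2-fold lower in high light and a partner at least 2-fold higher, 19 the reverse, and 38 went the same way. Level and length of both members were then removed by a straight-line fit on their log2 values. In these 955 pairs rho was then -0.16 in high light (permutation p 1.0e-05, the smallest 100000 permutations give, adjusted over 6 relations 2.0e-05). At low temperature rho was 0.08 (permutation p = 0.013, adjusted 0.019) and under combined stress -0.01 (permutation p = 0.822, adjusted 0.822). Pairs are not independent replicates, and with pieces under 5% of their partner left out rho was -0.21 in high light, 0.05 at low temperature (permutation p = 0.093) and -0.02 under combined stress (p = 0.453). At low temperature it was 0.13 in the 609 pairs with a piece at 10 to 50%.

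**Figure D4:**
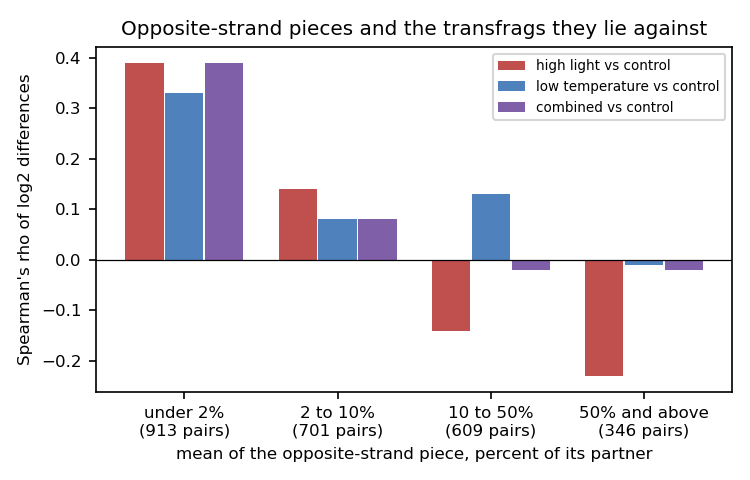
Spearman's rho between the log2 differences from control of opposite-strand pieces and of the transfrags they lie against (vertical axis), by the mean of the piece as a percentage of its partner (horizontal axis), for 3 comparisons. Pieces under 2% of their partner follow it in each comparison (0.39, 0.33 and 0.39), and for pieces of 50% or more rho was -0.23, -0.01 and -0.02; the differences between comparisons were not tested.

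In the 2151 weak transfrags whose libraries could be read back, control libraries had medians of 14.1 and 14.5 and high light libraries 9.63 and 11.7. Both high light libraries lay below both control libraries in 789 transfrags (36.7%) and above both in 327 (15.2%). Libraries that are alike in depth and level, without ties, would give 16.7% each way, but these differ in depth. Another scaling of the libraries would move both shares. The limma test with Benjamini-Hochberg adjustment called 0, with a smallest adjusted p of 0.25, and 85 higher and 267 lower had an unadjusted p under 0.05. That split depends on the scaling: it was 210 higher and 116 lower with libraries centred on the median of these transfrags, and 107 and 97 with quantile normalization. The same test called 0.0% of simulated 4-fold differences. Leaving out the shallower high light library gave 51 calls (2 higher and 49 lower), leaving out the deeper one 3. The control libraries correlated with each other at r = 0.22 across these transfrags. The deeper control library correlated with the high light libraries at 0.39 and 0.38, the shallower one at -0.00 and 0.04.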

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

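All tests of explanations in this part were chosen after the results were seen. In 6 named transfrags the difference made by light went one way at 30 °C and the other way at 24 °C. They were named for the largest interactions or the largest differences of combined stress from high light alone, which favours opposite directions. The difference between temperatures was not tested in any of them. Transfrag016066 had an interaction of 3.87, Transfrag004337 one of 3.48, Transfrag012767 one of -5.74 and Transfrag011365 one of -3.60 on the log2 scale. Transfrag001647 had an interaction of 3.31 and Transfrag019230 one of 2.53, and at 24 °C both were close to their level without light, at 1.09 and 1.14 times. Differences at 24 °C were also small for Transfrag011365 and Transfrag004337, at 0.644 and 1.73 times. The sum of all values was lower under combined stress than at low temperature, so the direction of Transfrag011365 may rest on the scaling. Transfrag012767 is among the 25 transfrags highest at low temperature alone.

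Weak transfrags had lower values in high light than in the control, while abundant ones had higher values. One high light library alone is argued against only for the lower values of weak transfrags under the deposited scaling. In 2151 transfrags read back by library, the high light libraries lay at -0.25 (95% interval -0.31 to -0.20) and -0.39. The interval is taken over transfrags and does not measure the spread between libraries. Another scaling of the libraries would move both levels, and the values of abundant transfrags could not be read back by library. A single wrong scaling factor is argued against only for the gap between weak and abundant transfrags, because it moves all transfrags alike. That gap was 0.83 (0.77 to 0.88) from transfrags of 10 to 50 to those of 1000 and above. Such a factor stays open for whether weak ones lie below the control or abundant ones above it. The medians of -0.28 and 0.55 became -0.83 and -0.04 with equal totals. A difference between libraries that is not the treatment stays open: the difference of the control libraries from each other correlated with that of high light from combined stress at r = 0.28 (0.24 to 0.31), where simulated unchanged groups reached 0.02. Light itself also stays open as an untested explanation, since 2 libraries per group cannot part it from the make-up of those libraries.

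Opposite-strand pieces followed their partners when they were weak beside them. Reads that kept the wrong strand may account for this. Under 2% of the partner the lowest rho of the 3 comparisons was 0.33, against 0.06 as the highest over all pairs at 10% or more. Within the latter, rho at low temperature was 0.13 in the 609 pairs at 10 to 50%. The 392 pieces opposite 71 partners of 10000 and above stood at a median of 1.79% of them. For stronger pieces in high light the relation was negative. A straight-line trend with log2 level and log2 length is argued against as its whole cause. With that trend removed rho was still -0.16 (-0.22 to -0.10), from -0.26 before. A curved trend was not removed and stays open. The interval treats pairs as independent, which they are not, so it may be too narrow. What gives the remaining relation stays open, antisense regulation included, which was not tested.

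In 25 transfrags the values were far higher at low temperature alone, where 100 simulations of unchanged groups reached at most 1. The spread between libraries stays open even so, because the simulations used a dispersion measured on weak transfrags and only 1 of the 25 has a mean at those levels. Whether both low temperature libraries carry the higher values cannot be told apart from one library carrying them, because reads could be weighed for only 10 pieces opposite 8 of the 25. For these, with the dispersion of 0.095, the log10 likelihood ratio favoured both libraries at 7.21, above the simulated range for one library (-10.03 to -0.27) and inside that for both (1.52 to 11.84). An effect of temperature that light cancels stays open and was not tested.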

How the results depend on the processing

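The scaling to equal totals, the limma test of recovered libraries, the dispersion found level by level and all alternatives for overlaps, regions, plasmid medians and the transfrags highest at low temperature alone were chosen after seeing the data; the other alternatives were fixed before. Of 163 values of named transfrags under alternatives, 137 moved by less than their expected SD, 26 by more (10 with a pseudocount of 10, 3 with quantile normalization, 13 with equal totals) and 0 changed sign. Of 96 values of main results, 57 stayed within the limits set, 36 moved, 1 lost its call and 2 reversed. Counts of transfrags were judged by their total and not by direction. High light with equal totals thus stayed within the limits, although 1536 higher and 2480 lower became 457 and 4888. A majority that turned, as in high light with a filter at 50, was entered as moved. The 2 reversed are correlations of pairs. Counts fall with a pseudocount of 10 because it shrinks differences of low values, and with a filter at a mean of 50 because fewer transfrags are tested; equal totals shift every transfrag of a group alike. For all other values the cause was not tested.

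For high light, low temperature, combined stress, the interaction, combined stress against high light and against low temperature, the transfrags at least 2-fold apart numbered 2328, 321, 674, 2875, 2412 and 552 with a pseudocount of 10, and 1626, 300, 626, 1800, 1612 and 517 with a filter at 50. That filter turned the majority in high light, to 984 higher and 642 lower. With equal totals they numbered 1089 for low temperature, 8445 for the interaction, 6205 and 2977 for the last pair. The excess of opposite-strand pieces at least 2-fold apart was 1.2, 0.5 and 5.7 points in the 3 stresses with a pseudocount of 10; with a filter at 50 it was 3.9 points at low temperature and 17.3 under combined stress, and with 90% overlap 9.5 under combined stress. In pairs whose piece reached 5% of its partner, rho was -0.21 in high light and -0.02 under combined stress, both reversed, and 0.05 at low temperature (permutation p = 0.093).

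Transfrags shared between the light differences at both temperatures numbered 229 with a pseudocount of 10. Between the temperature differences they numbered 69, then 86 with a filter at 50 and 84 with equal totals; between high light and low temperature 62, 72 and 437. Between high light and combined stress they numbered 261 and 276, and between low temperature and combined stress 108 and 124, with a pseudocount of 10 and a filter at 50. The limma test of recovered libraries made 1 call with a pseudocount of 10, and from 0 to 51 when each library was left out in turn, 51 without the shallower high light library; a lone library is then taken to vary like the other group. With the dispersion found level by level, simulated unchanged groups gave 947, 421, 628, 2032, 833 and 313 transfrags at least 2-fold apart in the 6 comparisons, in place of 1170, 754, 718, 2643, 1028 and 601. The observed 701 at low temperature lies between 421 and 754. Regions in high light numbered 68 with a pseudocount of 10, 68 with quantile normalization and 338 with equal totals, from 150. At low temperature they numbered 17 with equal totals, from 10. In high light, medians of pSYSM, pSYSA and pSYSG against transfrags of like level were -0.25, -0.57 and -0.51. They were -0.43, -0.77 and -0.66 with a filter at 50, and -0.23, -0.42 and -0.42 with a pseudocount of 10.

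No paired analysis was possible because the deposited columns carry no replicate numbers. Not run for want of values per library were the replicate block, leaving out libraries in the group values, fits to the groups of one comparison alone, count models, Fisher's exact test and an adjusted p of 0.1; gene lists had no names to match. Depth limits the weak transfrags: a value of 10 stands for about 4.8 reads in the shallower control library. Of 4-fold differences simulated for high light in weak transfrags, 86.0% reached 2 fold.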

Other observations

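The counts and correlations in this part were chosen after the data were seen. In high light, 50 transfrags were more than 3 times higher than in each other group and 548 more than 3 times lower, against 0.2 and 16.7 in simulations of unchanged groups. Of the 548, 466 had a mean under 50. Under combined stress 6 were higher in this way and 2 lower, against 0.2 and 1.2 in simulations, and in the control 4 and 9, against 0.2 and 7.6. At low temperature 29 were lower than in each other group, against 2.5 in simulations, and 26 of these had a mean under 50.

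Neighbouring transfrags on one strand had similar differences from the control, with Spearman's rho of 0.63 in high light, 0.36 at low temperature and 0.46 under combined stress over 8618 pairs. Over 5944 pairs of neighbours on opposite strands rho was -0.17, 0.06 and -0.00. For combined stress against high light alone it was 0.61 on the same strand and -0.29 on opposite strands. Pieces of one transcript are included among neighbours of one strand, and no test of these values across libraries could be made.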
